A study of Schizosaccharomyces pombe with 11 samples.

How the data were processed

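Transcription of wild-type fission yeast (Schizosaccharomyces pombe) was measured on Agilent tiling arrays whose 60-base probes cover both strands of the genome. Per the series description, RNA was hybridised directly to the arrays and the RNA:DNA hybrids were detected with an antibody, a method called HybMap, so no cDNA was made. The genome was split over 2 slide designs. Total RNA came from 4 conditions and poly(A)-selected RNA from 1, each with 2 replicates, which gave 20 single-colour RNA arrays. A further 2 arrays with both colours compared chromatin immunoprecipitated for histone H3 trimethylated at lysine 36 (H3K36me3) with input chromatin. The series description also names RNA polymerase II and total histone occupancy, which are not analysed here.

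The scanner files held intensity values from Agilent Feature Extraction, version 9.1.3.1 for total RNA and chromatin and 9.5.1.1 for poly(A) RNA, per the file headers. Processed intensity was background-subtracted by spatial detrending and was not normalised between arrays, per the file headers. For the chromatin arrays the processed intensities of both channels had also been dye-normalised by a linear method, and the deposited LogRatio column was the log10 of red over green, per the file headers. The deposited table of processed values in the series matrix was on a log2 scale by comparison with the scanner values. Its base line and combination of arrays were not stated. Each of its RNA columns followed the scanner signal of the probe on the opposite strand at the same position (Pearson r of 0.981 to 0.997 across probes), not that of the probe with the same number (-0.354 to 0.0696). Scanner values were therefore read by their own probe sequences, and table values were moved to the opposite strand. The median of the deposited table was 4.84 and 4.66 for standard samples on designs 1 and 2, 4.38 and 4.50 for heat shock, 4.28 and 4.21 for methyl methanesulfonate, 4.51 and 4.53 for minimal medium, and 2.51 and 2.39 for poly(A) RNA. The deposited chromatin column had a median of 0.17 and went with the mean log2 ratio of both arrays with a slope of 0.796 (r = 0.974), so its scale stays unknown.

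Every probe sequence was matched to both strands of the RefSeq genome (build ASM294v3, PomBase annotation). On designs 1 and 2, 231599 and 228043 of 241399 spots matched at 1 place, 8716 and 11434 matched at several, and 2 and 840 yeast probes had no match. Both designs also carried 1082 spots of zebrafish sequence, which served as a check of background. Strand was checked from the data: the median of probes complementary to coding RNA was 0.25 to 0.66 on the scaled log2 scale, and that of probes with the sequence of the RNA was -5.36 to -2.37. Probes with several matches, control spots and outlier spots were left out, and saturated spots were kept.

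A probe value was log2 of the processed signal minus the 75th percentile of its array. A gene value was the median over its unique sense-strand exon probes, with at least 4 probes, which left 11061 genes. No tRNA or snRNA gene had 4 such probes. All genes but 2 lay on 1 slide design. Antisense values used probes opposite the coding region of a protein-coding gene that lay in no annotated gene of that strand, again with at least 4 probes (2631 genes). A gene counted as saturated in a group when at least as many of its probes were saturated in both replicates as were not. It counted as dim when none of its probes was well above background in either replicate. For such genes the fold change is a bound written as "at least". Where the group was dim, the bound was computed against the lowest signal among probes well above background. That lowest signal, per array, is called the background floor. The same bound is given for named genes whose value lay under the floor in 1 or both replicates of a group, for sense and antisense signal, and no fold where both groups lay under it or the bound was under 1. Values under the floor have no order, so the named genes with a bound hold no rank. This second use of the floor was added after the results were seen.

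Arrays of both designs were joined into a replicate by an experiment number that they shared. For total RNA each experiment held 1 sample of every condition and had its own scan day, so the experiment was treated as a batch. Both arrays of a condition and design carried the same slide identifier, so slide and condition cannot be told apart. The deviations of samples from their group means went together within an experiment (r of 0.243 to 0.646 across 11061 genes over the pairs of groups), so the numbers paired the samples, and a fit with the experiment as a block is given as an alternative. The poly(A) arrays were run apart from the others and shared no experiment number with them, so RNA preparation and run cannot be told apart.

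Groups were compared with limma (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). The total-RNA groups shared 1 estimate of the spread with 4 residual degrees of freedom, and the poly(A) comparison used all 5 RNA groups with 5. Errors of log2 fold changes are standard errors of this fit and errors of levels are standard deviations. Differences between treatments were tested as contrasts of the same fit, without the shared standard samples. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. The share of probes well above background used the flag of the scanner software. The number of arrays limits the precision of every value.

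For H3K36me3, the log2 ratio of processed ChIP (Cy5) to input (Cy3) signal was centred on the median of each array. Probes inside protein-coding genes were compared with intergenic probes, the last with the first part of 3 equal parts of genes of at least 1500 bases (permutation within genes, 100000 resamples, 2-sided), and gene means with RNA levels (genes with at least 2 probes).

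Choices of groups, tests, gene lists, alternatives and named genes were fixed before the data were examined, except for the alternatives that the closing section names as added later. The rule named, for each RNA comparison, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold with every treated sample on the same side of every control sample, 3 and 3 ncRNA genes by the same rule, up to 4 members of each list with the smallest p, the 5 largest antisense rises and falls, and the 5 highest and 5 lowest H3K36me3 genes. Its further condition, the same sign on both slide designs, could not be applied because all genes but 2 lay on 1 design. Members outside the rule that are named to spell out a count of 5 or fewer were chosen after their values were seen. The lists covered chaperones, core environmental stress genes, oxidative stress genes of the Pap1 type, DNA repair, MBF targets (genes of the G1/S transcription factor), ubiquitin and the proteasome, ribosomal proteins, ribosome biogenesis, amino acid biosynthesis, purine and pyrimidine biosynthesis, thiamine-repressed genes, amino acid permeases, mating and meiosis, metal and phosphate uptake, glycolysis, hexose transport and glucose-repressed genes, the respiratory chain, sterol synthesis, histones, the unfolded protein response, and annotation classes (coding, other ncRNA, rRNA, snoRNA, Tf2 retrotransposon and mitochondrial genes). The ribosomal list was matched by name, so it also held the RNase P genes rpp1, rpp21 and rpp40 and the mitochondrial rps3. By name the amino acid list likewise held str3, which is a siderophore transporter gene and stood on the metal uptake list as well.

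The fit was tested on simulated data with every group at the standard mean, the spread of each gene in total RNA and independent normal noise. In the heat shock contrast 50 genes were shifted per step: 7 of 50 were called at a log2 shift of 0.5, 33 at 1, 48 at 2 and 49 at 3. Far fewer genes were shifted there than passed in the real comparisons, so these rates do not give the power of the real fits. Sharing of control samples was simulated with 20 sets of unchanged groups. Alternatives covered normexp background correction (offset 50), quantile normalisation within each design, scaling by the median of detected probes, centring on coding genes, filters on dim probes and on the number of probes, the mean of probes, each design alone, a variance trend, the block, only the groups compared, leaving out each replicate, a fold threshold of 2, coding genes alone, and the deposited table. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package (1.17.8).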

Results

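The series asked which parts of the fission yeast genome are transcribed in standard culture, how transcription changes under 3 other conditions, how poly(A)-selected RNA compares with total RNA, and how RNA compares with a chromatin mark. Standard cells were grown in rich medium with 2% glucose at 32 °C and collected at a culture density of 1.0. Heat-shocked cells, at a culture density of 1.0, were held at 40 °C for 15 min. Cells treated with methyl methanesulfonate (MMS), an alkylating agent that damages DNA, received 0.02% for 1 h at a culture density of 0.6. The remaining cells were grown in minimal medium, also with 2% glucose, at 32 °C and collected at a culture density of 1.0. Each of these 4 groups gave total RNA from 2 replicates, poly(A) RNA was selected from standard cells in 2 replicates, and H3K36me3 chromatin of standard cells was measured on 2 arrays.

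Each RNA array carried 240317 yeast spots. The median signal was 1240.2 to 2281 on the total-RNA arrays and 180.3 to 209.8 on the poly(A) arrays, against medians of 11.4 to 22.3 and 4.22 to 5.09 for negative control spots. In total RNA, on average 99.8% of coding-strand exon probes, 99.3% of antisense probes outside annotated genes and 89.0% of intergenic probes were well above background. The shares per replicate ranged from 98.5% to 99.6% for antisense probes and from 77.4% to 94.3% for intergenic probes. In poly(A) RNA the same shares were 97.7%, 58.3% and 54.0% (SD of 0.037, 1.19 and 0.785 percentage points, n = 2). The median scaled log2 signal of antisense probes was -2.63 in total RNA and -5.79 in poly(A) RNA, with coding probes at 0.25 and 0.52. These shares depended on the threshold: 9.70% of antisense and 7.94% of intergenic probes in total RNA lay above the 99th percentile of the zebrafish probes, with coding probes at 54.2%. Per replicate these shares ranged from 1.08% to 34.1%, 2.85% to 19.1% and 17.9% to 89.3%. That percentile was 1276 to 22518 on the total-RNA arrays, set by a few bright zebrafish probes (medians of 11.8 to 23.1). Whether these bind yeast transcripts was not tested, so the lower shares do not measure detection. The 95th percentile of the zebrafish probes was 138 to 1334 on the total-RNA arrays, where the 25th percentile of yeast spots was 510 to 1007. Signal above background can thus occur without a matching yeast sequence. The higher shares therefore do not by themselves measure transcription either.

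Heat shock was compared with standard culture to show which transcripts change in acute heat. Genes marked "at least" had a group under the background floor, or saturated, and hold no order among the largest changes. SPBC1289.14 (chromosome II, 4412241 to 4413599) rose 231-fold (log2 fold change 7.86 ± 0.13 SE, n = 2 against 2, adjusted p = 1.44e-07), lsd90 (SPBC16E9.16C; II, 1947985 to 1950255) rose 229-fold (7.84 ± 0.18, adjusted p = 4.38e-07), and gld1, which encodes glycerol dehydrogenase (I, 2174641 to 2176572), rose 71.1-fold (6.15 ± 0.15, adjusted p = 4.66e-07). The other coding genes with the largest rises were SPCC338.18, SPBC24C6.09C, ddr48 and SPACUNK4.17, which rose 77.3-fold to 132-fold. In the same group of 10, SPAC186.06, SPAC186.08C and SPAC186.04C rose at least 93.4-fold, 50.9-fold and 42.6-fold. The largest falls included gln1, which encodes glutamine synthetase and was 23.7-fold lower (-4.57 ± 0.23, adjusted p = 5.68e-06), SPBC887.17 (18.9-fold lower), dea2 (13.6-fold), the phospholipase gene plb2 (11.6-fold), grt1 (11.3-fold) and ani1 (10.9-fold). The iron uptake genes str1, fio1 and fip1 were 21.4-fold to 24.2-fold lower and str3 at least 9.92-fold lower, but their levels in the standard samples differed by an SD of 1.27 to 1.73 on the log2 scale (n = 2). Among ncRNA genes, prl61 rose at least 17.8-fold, SPNCRNA.1527 49.3-fold and SPNCRNA.3583 38.3-fold, while SPNCRNA.605 fell (-3.25), and SPNCRNA.604 and SPNCRNA.2043, which overlap or adjoin it on chromosome I, were at least 10.8-fold and 3.04-fold lower.

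Of 23 measured chaperone genes, 19 rose and 3 fell under heat shock (20 and 3 adjusted over the list alone), with a median log2 fold change of 1.51 against -0.20 for all coding genes. The disaggregase gene hsp104 rose at least 27.8-fold and the Hsp70 gene ssa1 at least 23.3-fold, both saturated after heat shock, and hsp78 and psi1 rose 25.9-fold and 20.3-fold. The 3 that fell were xdj1, mge1 and sks2. The list stood above other genes by camera (adjusted p = 4.84e-10, and adjusted p = 0.223 with an estimated correlation), and its median lay 1.69 and 1.59 above that of all other genes in experiments 1 and 2. Of 28 core environmental stress genes, 24 rose and none fell, also adjusted over the list alone (median 2.19; camera adjusted p = 5.45e-14, and adjusted p = 0.0307 with an estimated correlation). Among them ish1 rose 38.8-fold, ntp1, which encodes neutral trehalase, by 3.81 (log2), the glutathione peroxidase gene gpx1 12.3-fold, and rtc3 at least 16.5-fold with saturation. The core stress median lay 2.22 and 2.50 above that of all other genes in experiments 1 and 2. Of 18 oxidative stress genes of the Pap1 type, 9 rose, led by the catalase gene ctt1 (21.6-fold), and apt1, trx2 and caf5 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.00898, and adjusted p = 0.223 with an estimated correlation).

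Of 39 ubiquitin and proteasome genes 16 rose under heat shock, also adjusted over the list alone, among them the polyubiquitin gene ubi4 (at least 5.34-fold, saturated), cdc48 (2.11-fold) and ufd1 (2.43-fold), with a camera adjusted p = 0.000405, and adjusted p = 0.658 with an estimated correlation. Of 17 hexose transport and glucose-repressed genes 10 rose and ght8 and dak2 fell (10 and 3 adjusted over the list alone). The invertase gene inv1 rose 8.83-fold and the fructose bisphosphatase gene fbp1 4.29-fold (camera adjusted p = 0.00155, and adjusted p = 0.319 with an estimated correlation). Of 33 nuclear genes of the respiratory chain and ATP synthase 12 rose, such as cor1 (2.09-fold), and atp1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.658 with an estimated correlation). Of 12 mitochondrial genes cox1-I2b (2.03-fold) and rps3 (at least 2.15-fold, saturated) rose, of which the list alone kept 1. The test of that list is void, since 6 of its genes were saturated in both groups (camera adjusted p = 0.00898, and adjusted p = 0.658 with an estimated correlation; median 0.40, and 0.00 with quantile normalisation). The rise of rps3 ended without heat shock replicate 1 (adjusted p = 0.148), without standard replicate 2 (adjusted p = 0.159) and with quantile normalisation (adjusted p = 0.0643). Of 20 glycolysis and fermentation genes 7 rose, led by eno102 (35.8-fold) and pdc102 (at least 6.47-fold), and adh4, pdc101, adh1 and pfk1 fell (7 and 4 adjusted over the list alone). As a whole that list did not pass (camera adjusted p = 0.0774, and adjusted p = 0.658 with an estimated correlation). It passed by camera among coding genes alone (adjusted p = 0.0451). The single measured Tf2 retrotransposon, Tf2-11, rose 7.00-fold (2.81 ± 0.15, adjusted p = 7.1e-06).

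Of 115 ribosome biogenesis genes 106 fell under heat shock and none rose (107 fell and 1 rose adjusted over the list alone), with a median of -1.45, and -1.33 and -1.22 relative to all other genes in experiments 1 and 2. The helicase gene has1 was 5.32-fold lower and rpa43, which encodes a subunit of RNA polymerase I, 3.89-fold lower (camera adjusted p = 9e-22, and adjusted p = 0.264 with an estimated correlation). Of 137 genes on the ribosomal protein list 45 fell and rps3 rose (30 fell and none rose adjusted over the list alone), with rps2601 5.59-fold and rpl102 4.19-fold lower (camera adjusted p = 0.000197, and adjusted p = 0.658 with an estimated correlation). Of 24 sterol synthesis genes 14 fell, such as erg7 (3.88-fold lower) and hmg1 (2.60-fold lower), and scp1 and erg1 rose (14 and 2 adjusted over the list alone; camera adjusted p = 0.00713, and adjusted p = 0.658 with an estimated correlation). Members of the list of unfolded protein and endoplasmic reticulum genes went both ways. Of 13, 7 were lower, gas1 by 5.14-fold, and ero11, bip1, hrd1, gas2 and cnx1 were higher. The counts were the same adjusted over the list alone (camera adjusted p = 0.749). Of 3 rRNA genes SPRRNA.32 fell (-0.96 ± 0.23, adjusted p = 0.00881), a call that ended without heat shock replicate 2 (adjusted p = 0.058), without standard replicate 1 (adjusted p = 0.0632) or centred on coding genes (adjusted p = 0.0596), and none of 7 snoRNA genes passed. With the experiment as a block the snoRNA gene SPNCRNA.1483 (adjusted p = 0.0195) and the mitochondrial genes cox1-I1b and atp6 (adjusted p = 0.000535 and 0.00104, atp6 saturated after heat shock) passed as well. The list alone kept the same call. The other 2 rRNA genes, rns and rnl, and the snoRNA gene snR30 were saturated in both groups, so their differences were not measured and the test of the rRNA list is void (median 0.34, mean -0.09, camera adjusted p = 0.758).

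In all, 5835 of 11061 genes passed under heat shock, 2359 higher and 3476 lower. Of 4975 protein-coding genes 1131 rose and 1880 fell, and of 6064 ncRNA genes 1214 rose and 1595 fell. Neither class stood apart from other genes (camera adjusted p = 0.261 for coding and 0.269 for other ncRNA genes). All called genes had the same sign in both experiments, with r = 0.941 between the fold changes of the experiments across genes. A call rests on the mean of both experiments, so a shared sign is largely built into it, here and in the later comparisons. With the experiment as a block 7117 genes passed. Centring each replicate on coding genes turned the split to 2802 higher and 2283 lower, since it moved the median of all genes from -0.15 to 0.03 (log2).

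**Figure D1:**
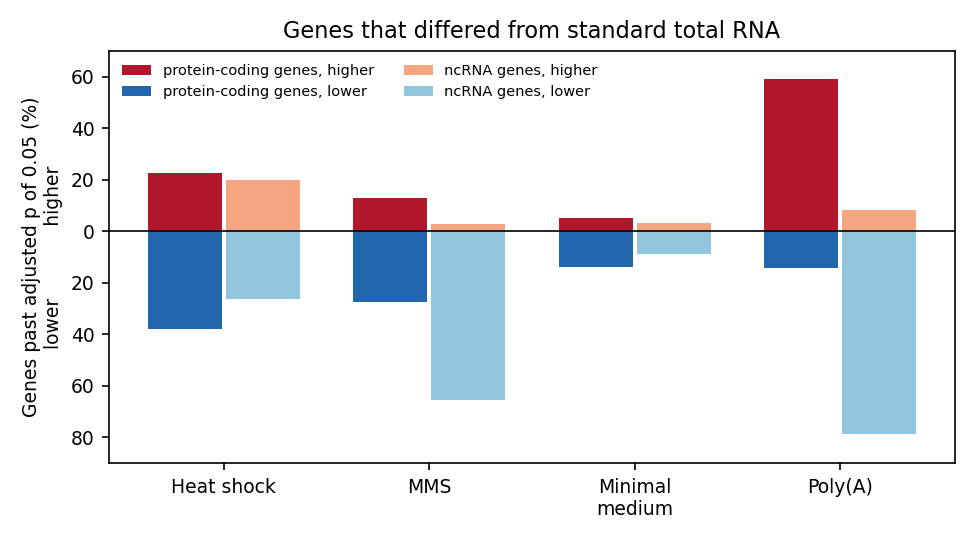
Share of coding and ncRNA genes higher (above the line) and lower (below the line) at adjusted p under 0.05 (limma, n = 2 against 2) in heat shock, MMS and minimal medium against standard total RNA, and in poly(A) against total RNA of standard cells. After MMS 65.6% of ncRNA genes were lower and 2.72% higher, and in poly(A) RNA 78.8% were lower and 8.18% higher, splits that moved with quantile normalisation.

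MMS was compared with standard culture to show the response to DNA damage. On chromosome I, gdt1 (SPAC186.05C; 5540032 to 5541481) rose 47.6-fold (5.57 ± 0.15, n = 2 against 2, adjusted p = 5.38e-06), its neighbours SPAC186.06 and SPAC186.04C rose at least 35.5-fold and 9.73-fold, and the haem uptake gene shu1 rose at least 19.8-fold. The sulfiredoxin gene srx1 (SPBC106.02C) rose 29.9-fold (4.90 ± 0.42, adjusted p = 0.000564), the glutathione transferase gene gst2 17.4-fold, ctt1 13.4-fold and aes1 14.8-fold. The iron uptake genes str3 and frp1 were 21.6-fold and 21.4-fold higher, with an SD of 1.73 and 1.00 between the standard samples. The largest falls included pfl3 (6.17-fold lower, -2.62 ± 0.17, adjusted p = 0.000216), the subtelomeric helicase gene tlh2 (6.10-fold), mei2, a regulator of meiosis (4.03-fold), efm6 (3.91-fold), grt1 (3.55-fold), cts2 (3.50-fold) and SPBPB8B6.02C (at least 2.76-fold). SPBC16G5.19 was at least 1.27-fold lower and not well above background after MMS, and lost its call with normexp (adjusted p = 0.068). SPAC869.03C was lower and under the background floor after MMS, too dim in both groups for a fold, and lost its call with an intensity trend in eBayes (adjusted p = 0.149). SPBC12C2.14C (at least 2.10-fold lower) lost it without MMS replicate 1 (adjusted p = 0.0565), without MMS replicate 2 (adjusted p = 0.0602) and without standard replicate 1 (adjusted p = 0.102), and also with normexp (adjusted p = 0.0871), quantile normalisation (adjusted p = 0.0805) and the mean of probes (adjusted p = 0.149). Among ncRNA genes SPNCRNA.3897 and SPNCRNA.5420 rose 9.28-fold and 8.70-fold, and SPNCRNA.5455 was 6.33-fold and SPNCRNA.2674 and aal1 at least 2.77-fold and 5.66-fold lower. SPNCRNA.4900 rose 12.2-fold, a call that ended without MMS replicate 1 (adjusted p = 0.0858), without standard replicate 1 (adjusted p = 0.0601) or without standard replicate 2 (adjusted p = 0.076).

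Of 23 MBF targets and nucleotide supply genes 15 rose after MMS and none fell, also adjusted over the list alone, with a median of 0.80 against -0.16 for all coding genes. The ubiquitin ligase gene cdt2 rose 4.64-fold, the replication licensing gene cdc18 3.39-fold, the histone regulator ams2 3.67-fold and the cyclin gene cig2 2.42-fold (camera adjusted p = 1.42e-15, and adjusted p = 0.159 with an estimated correlation). Of 53 DNA repair and checkpoint genes 7 rose and 14 fell (7 and 10 adjusted over the list alone). Those that rose included the recombination gene rad54 (2.26-fold) and the translesion polymerase gene kpa1 (2.47-fold), while the checkpoint kinase gene chk1 was 1.67-fold lower. The median and mean of the repair list were -0.16 and -0.10, yet camera placed it above all other genes (adjusted p = 0.025, and adjusted p = 0.429 with an estimated correlation), whose median was -0.41; among coding genes alone its direction turned down (adjusted p = 0.804). Of 28 core stress genes 15 rose and none fell, also adjusted over the list alone, such as hsp16 (7.45-fold) and ish1 (4.16-fold; camera adjusted p = 1.53e-19, and adjusted p = 0.00794 with an estimated correlation). Of 18 Pap1-type genes 13 rose, such as gst3 (3.25-fold) and caf5 (3.79-fold), and apt1 and gst1 fell, the same adjusted over the list alone (camera adjusted p = 4.35e-15, and adjusted p = 0.00794 with an estimated correlation). Relative to all other genes, the medians in experiments 1 and 2 were 1.11 and 1.24 for the MBF list, 1.30 and 1.37 for the core stress list and 2.11 and 1.89 for the Pap1 list.

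Of 39 ubiquitin and proteasome genes 17 rose after MMS, led by ubi4 (3.15-fold), and 10 rose adjusted over the list alone (camera adjusted p = 4.29e-17, and adjusted p = 0.159 with an estimated correlation). Of 10 histone genes 6 rose, also adjusted over the list alone, such as hhf1 (1.43-fold) and pht1 (1.51-fold; camera adjusted p = 1.59e-07, and adjusted p = 0.159 with an estimated correlation), with pht1 losing its call without MMS replicate 2 (adjusted p = 0.0624). Of 20 glycolysis and fermentation genes eno102 (8.13-fold), pdc102 (at least 1.39-fold) and zwf1 (3.54-fold) rose, and pdc201 fell, of which the list alone kept the 3 rises (camera adjusted p = 6.52e-07, and adjusted p = 0.159 with an estimated correlation). Leaving out any MMS or standard sample ended the call of pdc201 (adjusted p of 0.082 to 0.142), as did quantile normalisation (adjusted p = 0.635) and scaling by detected probes (adjusted p = 0.0977). Of 115 ribosome biogenesis genes 101 fell and none rose (103 fell adjusted over the list alone), with rrp3 2.30-fold and mpp10 2.11-fold lower (camera adjusted p = 1.02e-07, and adjusted p = 0.379 with an estimated correlation). Of 137 ribosomal protein genes 19 fell and none rose (5 fell adjusted over the list alone), such as rpl3002 (2.47-fold lower). Their median of -0.23 lay above that of all genes and below that of coding genes. Camera therefore gave an upward direction over all genes (adjusted p = 0.467, and adjusted p = 0.899 with an estimated correlation). Among coding genes its direction was downward (adjusted p = 0.0143). Of 33 respiratory genes atp14 and atp15 rose and cox6 and atp20 fell, none of them adjusted over the list alone, and all 4 calls ended when 1 sample was left out. The median and mean of the respiratory list were -0.03 and -0.02 (camera upward, adjusted p = 0.00022, and adjusted p = 0.379 with an estimated correlation). Among coding genes alone the list did not pass (adjusted p = 0.155), and its median was 0.11 when scaled by detected probes, 0.05 when centred on coding genes and 0.06 in the deposited table.

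The endoplasmic reticulum list did not pass after MMS (ero11 2.12-fold higher, gas1 2.46-fold and pmt1 1.37-fold lower, the same counts adjusted over the list alone; median -0.10, camera upward, adjusted p = 0.0927). Without MMS replicate 2 (adjusted p = 0.067) or standard replicate 1 (adjusted p = 0.0561) the call of pmt1 ended. In the block fit pdi5 passed as lower (adjusted p = 0.0275). None of 12 mitochondrial genes passed, over all genes or the list alone. The test of that list is void, since 6 of its genes were saturated in both groups (median 0.09, camera adjusted p = 0.00116, adjusted p = 0.443 with an estimated correlation and adjusted p = 0.111 among coding genes alone). With the experiment as a block cox1-I2b and cox1-I1b rose (adjusted p = 0.00743 and 0.0147). Of 3 rRNA genes SPRRNA.32 fell (-0.62 ± 0.23, adjusted p = 0.0477) and of 7 snoRNA genes SPNCRNA.1650 fell (-0.71 ± 0.22, adjusted p = 0.0272), with neither call kept over the list alone or without any 1 of the MMS or standard samples. With the experiment as a block the snoRNA gene SPNCRNA.723 rose (adjusted p = 0.0035) and SPNCRNA.1483 fell (adjusted p = 0.0436). The median and mean of the rRNA list, with rns and rnl saturated in both groups, were 0.02 and -0.18 (camera upward, adjusted p = 0.467), and those of the snoRNA list -0.01 and -0.02 (camera upward, adjusted p = 0.119). Tf2-11 rose 2.90-fold (1.54 ± 0.15, adjusted p = 0.000771).

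In all, 6147 of 11061 genes passed after MMS, 799 higher and 5348 lower. Coding genes split into 632 higher and 1366 lower, and ncRNA genes into 165 higher and 3975 lower. Camera placed coding genes above other genes (adjusted p = 2.79e-17, and adjusted p = 0.188 with an estimated correlation) and other ncRNA genes below them (adjusted p = 2.23e-17, and adjusted p = 0.235 with an estimated correlation). All called genes had the same sign in both experiments (r = 0.883 across genes), and 7543 genes passed with the experiment as a block. With quantile normalisation 3501 genes passed, 1073 higher and 2428 lower, and the median of ncRNA genes moved from -0.62 to -0.21. The count also fell without MMS replicate 2 or without standard replicate 1.

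**Figure D2:**
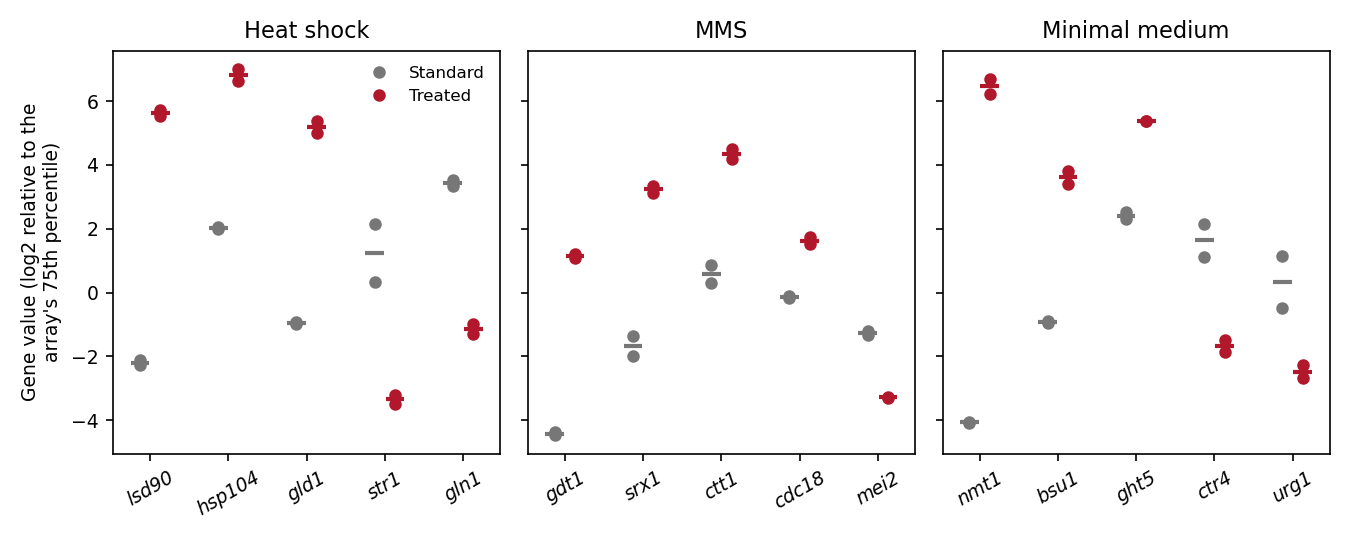
Level of 5 named genes per comparison in standard (grey) and treated (red) cells, as log2 signal relative to the 75th percentile of each array; points are the 2 replicates and lines their means. The standard replicates of str1 and urg1 lay apart (SD of 1.27 and 1.15), and hsp104 and nmt1 were saturated after treatment.

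Minimal medium was compared with rich medium to show which transcripts differ between the media. The thiamine synthesis gene nmt1 (SPCC1223.02; III, 1838415 to 1839664) rose at least 1479-fold and thi2 (II, 3940526 to 3941699) at least 121-fold, both saturated in minimal medium (adjusted p = 1.46e-07 and 1.03e-05), and bsu1, a vitamin B6 transporter gene, rose 23.3-fold (4.55 ± 0.16, adjusted p = 1.03e-05). SPCC794.03 rose 104-fold, SPBPB2B2.06C 74.4-fold, SPAC212.08C 27.2-fold, SPAC27D7.11C 26.7-fold, SPBPB2B2.08 26.6-fold and aes1 11.5-fold. The siderophore transporter gene str3 was 20.7-fold higher (adjusted p = 0.0222), a call that ended without minimal medium replicate 1 (adjusted p = 0.0557) or standard replicate 2 (adjusted p = 0.132), or with only the groups compared (adjusted p = 0.065). The largest falls were in urg2 (20.7-fold lower, -4.37 ± 0.39, adjusted p = 0.000549) and urg1 (7.03-fold), both known as uracil-regulated genes, in the copper transporter gene ctr4 (9.96-fold), in the peptide transporter gene ptr2 (8.33-fold), and in SPAC977.15, pfl9, SPAC977.14C, SPAPB24D3.07C and grt1 (9.62-fold to 14.8-fold). SPAC869.01 was at least 2.93-fold lower, a call that ended without standard replicate 2 (adjusted p = 0.0735). Among ncRNA genes SPNCRNA.6628 rose at least 12.4-fold and omt3 13.1-fold, and SPNCRNA.284, SPNCRNA.2030 and SPNCRNA.1310 were 11.5-fold, 8.32-fold and 8.29-fold lower. SPNCRNA.2041 rose 10.7-fold, a call that ended without standard replicate 2 (adjusted p = 0.123) or with only the groups compared (adjusted p = 0.053).

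Of 14 thiamine-repressed and vitamin genes 10 rose and none fell (11 and 1 adjusted over the list alone), with a median of 1.21 against -0.18 for coding genes (camera adjusted p = 5.1e-20, and adjusted p = 0.0444 with an estimated correlation). The thiamine transporter gene thi9 rose 8.61-fold. Of 17 hexose transport and glucose-repressed genes 8 rose and ght8 fell (9 and 1 adjusted over the list alone), with ght5 7.82-fold, inv1 6.07-fold and ght1 4.79-fold higher (camera adjusted p = 3.44e-08, and adjusted p = 0.131 with an estimated correlation). Of 33 mating and meiosis genes 9 rose, such as mei2 (2.82-fold), and ste6, map2, jnm1 and crs1 fell (12 and 5 adjusted over the list alone; camera adjusted p = 5.1e-06, and adjusted p = 0.0444 with an estimated correlation). The fall of ste6 ended without standard replicate 2 (adjusted p = 0.0803). Of 20 metal and phosphate uptake genes 7 rose, such as the zinc transporter gene zrt1 (2.86-fold), and the copper transporter genes ctr4, ctr5 (6.05-fold lower) and ctr6 and the siderophore gene sib3 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.000379, and adjusted p = 0.175 with an estimated correlation). Of 17 amino acid permeases and transporters 6 rose, such as isp5 (4.67-fold) and the ammonium transporter gene amt1 (2.48-fold), and ptr2 fell (6 and 2 adjusted over the list alone). That list had a median of 0.00 and a mean of 0.13 (camera adjusted p = 0.00785, and adjusted p = 0.719 with an estimated correlation), and its median was -0.01 when scaled by detected probes. Relative to all other genes, the medians in experiments 1 and 2 were 1.34 and 1.46 for the thiamine list and 0.54 and 0.57 for the hexose list.

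Amino acid synthesis genes did not move as a group in minimal medium: of 77, 10 rose and 7 fell (11 and 7 adjusted over the list alone). Among the rises met17 was 3.44-fold, gdh2 2.66-fold and met1 2.24-fold higher, and the siderophore transporter gene str3 was counted as well. The list, with str3 in it, had a median of -0.14, a mean of -0.02 and an upward camera test (adjusted p = 0.182). Of 19 purine and pyrimidine synthesis genes 7 fell, such as ura3 (2.87-fold lower), and none rose (12 fell adjusted over the list alone; camera adjusted p = 0.00517, and adjusted p = 0.804 with an estimated correlation). Without standard replicate 2 the calls of ura3, ura5, ade5 and ura1 ended (log2 fold changes of -1.385, -0.535, -0.662 and -0.822). Those of ura5, ade5 and ura1 also ended without standard replicate 1 (-0.72, -0.69 and -0.749). Of 115 ribosome biogenesis genes 88 fell and none rose (100 fell adjusted over the list alone), with ebp2 2.81-fold and rrp4 2.01-fold lower (camera adjusted p = 5.1e-20, and adjusted p = 0.253 with an estimated correlation). Of 137 ribosomal protein genes 27 fell and none rose (80 fell adjusted over the list alone), with rpl1603 2.10-fold lower (camera adjusted p = 4.65e-09, and adjusted p = 0.719 with an estimated correlation). Of 20 glycolysis genes pdc201 rose (3.09-fold) and eno102 fell (2.29-fold lower), and pdc102 passed as well, the same adjusted over the list alone. The list had a median of -0.00, a mean of 0.08 and an upward camera test (adjusted p = 0.0418, and adjusted p = 0.719 with an estimated correlation). Its median was 0.07 with quantile normalisation, 0.14 centred on coding genes and 0.03 in the deposited table. The levels of pdc102 lay under the background floor in both media, so neither a direction nor a fold is given. Its call ended with normexp (adjusted p = 0.0533), quantile normalisation (adjusted p = 0.162) and an intensity trend in eBayes (adjusted p = 0.125), as well as without standard replicate 1 (adjusted p = 0.0677) or standard replicate 2 (adjusted p = 0.098).

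The remaining lists did not pass in minimal medium. Of 33 respiratory genes atp20 and cor1 fell and none was kept over the list alone (median -0.10, camera upward, adjusted p = 0.988), and both calls ended without standard replicate 1 or without standard replicate 2 (adjusted p of 0.0894 to 0.174). Fitted with the experiment as a block, cyc1 (adjusted p = 0.0118) and cox6 (adjusted p = 0.0334) fell as well, and both also passed with normexp, the mean of probes and coding genes alone. Of 24 sterol genes erg32 rose and hem13, a haem synthesis gene, fell, also adjusted over the list alone (median -0.19, camera upward, adjusted p = 0.988); the call of erg32 ended without standard replicate 1 (adjusted p = 0.0767) or standard replicate 2 (adjusted p = 0.0848). In the block fit erg8 fell (adjusted p = 0.0151) and erg28 rose (adjusted p = 0.0148), and both also passed with the mean of probes and coding genes alone. None of 3 rRNA genes and none of 12 mitochondrial genes passed, over all genes or over each list alone (camera adjusted p = 0.988 and 0.168), with 1 and 5 of them saturated in both groups. SPRRNA.32 fell with the experiment as a block (adjusted p = 0.044). Of 7 snoRNA genes SPNCRNA.1483 and SPNCRNA.1650 fell (3 fell adjusted over the list alone; camera adjusted p = 0.988), both calls ending without standard replicate 1 (adjusted p = 0.17 and 0.203). With the experiment as a block snR90 fell and SPNCRNA.723 rose (adjusted p = 0.0315 and 0.0245). Tf2-11 did not pass (0.44 ± 0.15, adjusted p = 0.0857) and passed with the experiment as a block (adjusted p = 0.0234).

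In all, 1682 of 11061 genes passed in minimal medium, 455 higher and 1227 lower, with coding genes at 253 and 692 and ncRNA genes at 197 and 533. Neither class stood apart from other genes (camera adjusted p = 0.988 for both). All called genes had the same sign in both experiments (r = 0.791 across genes). The count rested on the samples in the fit: 3739 genes passed with the experiment as a block, 477 without standard replicate 1, 380 without standard replicate 2, 1033 without minimal medium replicate 2, and 787 with only the groups compared. Centring on coding genes gave 483 higher and 427 lower.

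**Figure D3:**
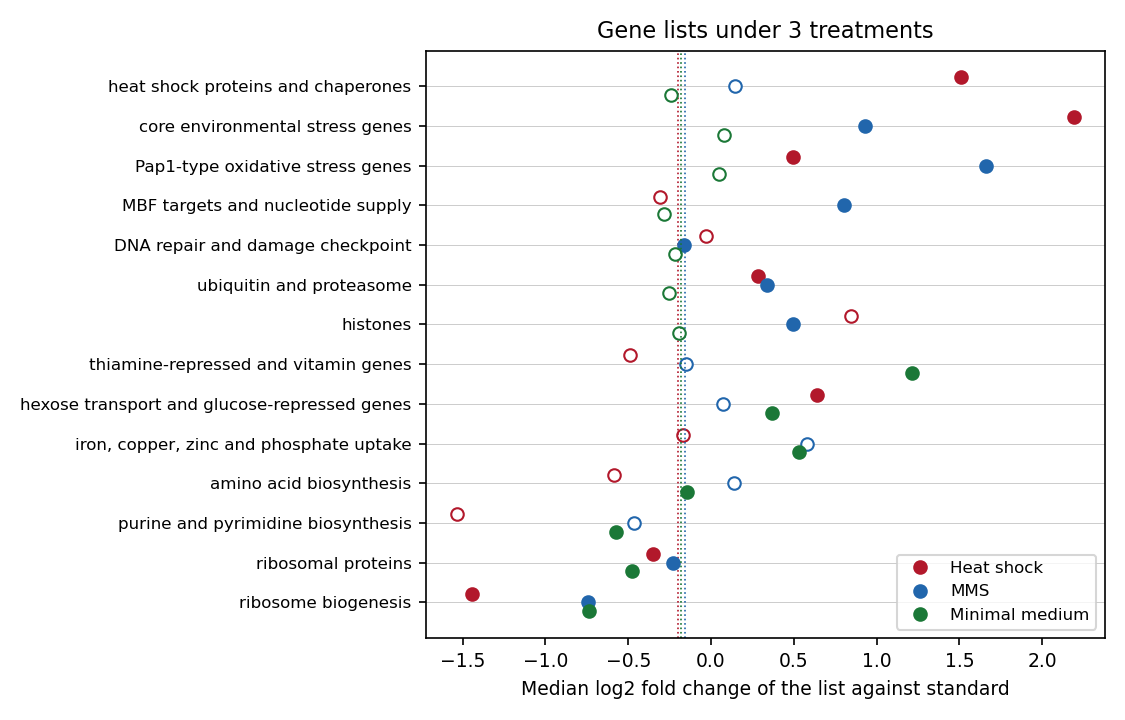
Median log2 fold change of 14 gene lists in heat shock, MMS and minimal medium against standard culture (n = 2 against 2). Filled points are lists fixed for that comparison, open points are other lists, and dotted lines mark the median of coding genes (-0.20, -0.16 and -0.18). The core stress list lay at 2.19 in heat shock and 0.93 after MMS, and the ribosome biogenesis list at -1.45, -0.74 and -0.74 (heat shock, MMS, minimal medium).

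The treatments were then set against each other without the standard samples. Between heat shock and MMS 5987 genes differed, and 1198 coding genes were higher and 1402 lower in heat shock. Of 23 chaperone genes 19 were higher and 2 lower in heat shock than in MMS, and of 28 core stress genes 23 and 2. Of 23 MBF targets 18 were lower and 1 higher in heat shock, of 115 ribosome biogenesis genes 84 and 4, and of 18 Pap1-type genes 8 and 5. Between heat shock and minimal medium 4864 genes differed, with 12 of 14 thiamine-repressed genes lower and none higher in heat shock, and 27 of 39 ubiquitin and proteasome genes higher and none lower. Between MMS and minimal medium 3896 genes differed (898 higher and 816 lower with quantile normalisation, against 861 and 3035), with 19 of 23 MBF targets, 12 of 18 Pap1-type genes and 31 of 39 ubiquitin and proteasome genes higher in MMS and none, 1 and none lower. Between heat shock and MMS the quantile split was 2412 higher and 2604 lower, against 4383 and 1604. Against the standard samples, heat shock and MMS shared 421 coding rises and 928 falls, where independent lists would share 143.7 and 516.2. Heat shock and minimal medium shared 138 rises and 532 falls (57.5 and 261.5 if independent), and MMS and minimal medium 128 and 461 (32.1 and 190.0). Across 4975 coding genes the fold changes of these pairs had r of 0.584, 0.35 and 0.404 and covariances of 0.39, 0.222 and 0.14; 20 simulated sets of unchanged groups against shared controls gave a mean r of 0.5, a covariance of 0.0161 and no shared calls. The simulated sets held no changed gene, so they do not show how many shared calls the controls add where genes do change. The 2 standard samples cannot be split between comparisons, so part of the excess may come from the shared controls.

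Antisense signal was measured opposite 2631 coding genes to show whether it followed the sense transcripts. Under heat shock it rose at 523 genes and fell at 824, after MMS at 78 and 1923, and in minimal medium at 75 and 198. Across genes, changes of antisense and sense signal went together (Pearson r of 0.813, 0.644 and 0.619; Spearman rho of 0.774, 0.585 and 0.507), with genes not being independent replicates. At some genes antisense signal passed and sense signal did not, and the difference between strands was not tested. Opposite SPAC8E11.12 (I, 3374696 to 3375004) antisense signal rose 56.2-fold under heat shock (5.81 ± 0.48, n = 2 against 2, adjusted p = 6.51e-06) with a sense change of -0.11 (adjusted p = 0.552). In minimal medium antisense signal rose 8.84-fold at SPAC57A7.05 and 8.15-fold at mug114, with sense changes of -0.14 (adjusted p = 0.565) and 0.64 (adjusted p = 0.186). After MMS it was at least 2.98-fold lower at SPCC1235.17 with a sense change of -0.30 (adjusted p = 0.506). The other antisense rises named by the rule under heat shock lay at lsd90 (12.9-fold) and at SPAC186.08C, SPAC186.07C and SPAC186.04C (at least 4.09-fold, 6.99-fold and 5.95-fold), where sense signal rose as well. The named falls lay at SPBC887.17, str1 and fio1 (6.17-fold to 9.81-fold lower) and at SPBPB10D8.01 and grt1 (at least 8.15-fold and 3.98-fold lower). After MMS the named antisense rises lay at gdt1 (10.5-fold), frp1, str3 (at least 8.80-fold), shu1 (at least 2.38-fold) and SPAC186.04C (at least 1.95-fold), and the other named falls at pfl3, grt1 (at least 4.16-fold lower), mei2 (at least 4.19-fold) and SPBPB8B6.02C (at least 1.03-fold). The call of SPBPB8B6.02C ended with normexp (adjusted p = 0.0504). In minimal medium the other named rises lay at SPBPB2B2.06C, sul2 and str3 (at least 9.86-fold) and the named falls at SPAC750.01 (5.05-fold lower), yhb1, grt1 (at least 3.69-fold), pfl9 (at least 1.87-fold) and pfl7 (at least 2.58-fold).

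With the experiment as a block 1577, 2114 and 548 antisense changes passed in heat shock, MMS and minimal medium. All called changes had the same sign in both experiments (r of 0.909, 0.814 and 0.668). Without genes whose sense signal passed, 115 of 1035, 1251 of 1622 and 31 of 2135 antisense changes passed. With quantile normalisation MMS gave 136 higher and 405 lower and minimal medium 69 and 87. The direction in minimal medium rested on single samples: the split of 75 higher and 198 lower became 73 and 40 without standard replicate 1, 26 and 26 without standard replicate 2, and 62 and 77 without minimal medium replicate 2. Single samples also decided the antisense calls of shu1 after MMS (adjusted p = 0.0554 without MMS replicate 1 and 0.0658 without standard replicate 2) and of grt1 (adjusted p of 0.085 to 0.117 without either standard sample or minimal medium replicate 2) and pfl9 (adjusted p = 0.0669 without standard replicate 2) in minimal medium, where that of pfl9 also ended with normexp (adjusted p = 0.115).

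Poly(A)-selected RNA was compared with total RNA of standard cells to show which transcripts the selection keeps. By median log2 fold change, coding genes gained signal relative to the 75th percentile of each array (0.57), and ncRNA and mitochondrial genes lost it (-2.14 and -3.69). Of coding genes 14.2% were lower, and of ncRNA genes 8.18% were higher. The ncRNA median turned to 0.15 with quantile normalisation. The mitochondrial list did not pass by camera with an estimated correlation (adjusted p = 0.593). The ribosomal protein gene rpp102 (II, 4008717 to 4009396) was 10.5-fold higher in poly(A) RNA (3.39 ± 0.19, n = 2 against 2, adjusted p = 1.45e-07), followed by vma10 (10.3-fold), tim13 (10.0-fold), rpl3602, rpl35, rpl3801, snu13, rpl3703, rpl3601 and rps1801 (7.77-fold to 9.33-fold). The mitochondrial gene atp6 was 73.4-fold lower (-6.20 ± 0.41, adjusted p = 4.16e-07), as were cox1-I1b (39.1-fold), the mitochondrial rps3 (26.8-fold) and cox1-I2b (22.6-fold). Further coding genes that fell were SPAC2F3.07C (at least 8.72-fold lower), mug112 (at least 8.88-fold), trp663 (at least 4.79-fold, a call that ended with quantile normalisation, adjusted p = 0.0747), mde7 (at least 10.1-fold) and mug62 (at least 11.7-fold), and SPAC22F8.03C was at least 7.34-fold lower and not well above background in poly(A) RNA. Among ncRNA genes SPNCRNA.942 and SPNCRNA.137 were 7.17-fold and 5.58-fold higher, and SPNCRNA.7540, SPNCRNA.7539 and SPNCRNA.7683 were at least 25.1-fold, 21.5-fold and 37.6-fold lower. SPNCRNA.2101 was 4.92-fold higher but changed sign with the mean of its probes (-0.02, adjusted p = 0.896).

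Of 137 genes on the ribosomal protein list 135 were higher in poly(A) RNA and the mitochondrial rps3 lower, also adjusted over the list alone, with a median of 2.29 against 0.57 for coding genes (camera adjusted p = 3.3e-33, and adjusted p = 0.124 with an estimated correlation). With quantile normalisation these medians were 0.81 and 0.51. At the exon lengths of the list its median was 2.30, against 1.39 for other coding genes of those lengths. All 10 histone genes were higher, also adjusted over the list alone, such as hhf3 (7.17-fold) and hht3 (6.60-fold; camera adjusted p = 3.21e-06, and adjusted p = 0.124 with an estimated correlation), with a median of 2.07, and 1.21 with quantile normalisation. Of 12 mitochondrial genes 10 were lower and the small rRNA gene rns higher, also adjusted over the list alone, with a median of -3.69 (camera adjusted p = 0.0128, and adjusted p = 0.593 with an estimated correlation). Of these 12 genes 5 were saturated in total RNA, so their differences are bounds. The median and the test of the list rest in part on these clipped values. The direction of rns turned with quantile normalisation (-0.28, adjusted p = 0.0448), and its probes were outside the measured range in total RNA, so its rise was not measured. Of 7 snoRNA genes snR90, SPNCRNA.1650, SPNCRNA.1483, SPNCRNA.723 and snR101 were lower and snoR61 higher, also adjusted over the list alone (median -1.41, camera adjusted p = 0.726). The fall of SPNCRNA.1650 ended with quantile normalisation (-0.02, adjusted p = 0.943) and the rise of snoR61 with the mean of probes (adjusted p = 0.145). Of 3 rRNA genes SPRRNA.32 was 10.4-fold lower and rns higher, also adjusted over the list alone (median -0.48, camera upward, adjusted p = 0.859). The remaining gene, rnl, was saturated in total RNA and passed as lower with normexp (adjusted p = 0.0305), quantile normalisation (adjusted p = 4.81e-06), the mean of probes (adjusted p = 0.00876), centring on coding genes (adjusted p = 0.00877) and without poly(A) replicate 1 (adjusted p = 0.0213). With at least 1 probe per gene 19 rRNA genes had a value, of which 16 rose and 2 fell (median 2.33). Saturation of these genes was not counted. On the standard total-RNA arrays 0.20% to 0.51% of yeast spots were saturated, against at most 0.0004% on the poly(A) arrays. Clipped values in total RNA can therefore be part of these rises, which do not show that the selection kept rRNA. Tf2-11 was 1.64-fold higher (adjusted p = 0.00147), a call that ended with quantile normalisation (adjusted p = 0.301) and with centring on coding genes (adjusted p = 0.332).

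In all, 8935 of 11061 genes differed between poly(A) and total RNA, 3448 higher and 5487 lower. Of 4975 coding genes 59.2% were higher and 14.2% lower, and of ncRNA genes 496 were higher and 4778 lower. Camera placed coding genes above (adjusted p = 6.61e-77, and adjusted p = 0.0185 with an estimated correlation) and other ncRNA genes below all others (adjusted p = 2.77e-77, and adjusted p = 0.0206 with an estimated correlation). The direction of the ncRNA median of -2.14 turned to 0.15 with quantile normalisation, which gave 5411 genes higher and 2615 lower. The split was 4914 and 4569 when scaled by detected probes and 1932 and 6713 when centred on coding genes, and preparation and array run cannot be told apart.

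H3K36me3, a histone mark laid down along transcribed genes, was measured against input chromatin to set chromatin beside the transcriptome. Its median log2 ratio was 0.30 over 30307 probes in coding genes and -2.83 over 2789 intergenic probes, a difference of 3.13 (3.42 and 2.72 on arrays 1 and 2). The difference was 1.03 with loess within each array. Along 2581 genes of at least 1500 bases the medians of the first, middle and last parts were 0.11, 0.52 and 0.15. The last part did not differ from the first past the threshold (median difference 0.02, 2-sided permutation p = 0.0975), though it did with loess (0.04, permutation p = 0.0163). Without loess 51.6% of genes were higher in the last part, and the difference was 0.03 on array 1 and -0.00 on array 2. The mark rose with RNA level across 4429 genes (Spearman rho = 0.376 and Pearson r = 0.418; rho of 0.366 and 0.351 on arrays 1 and 2), genes not being independent replicates. With the genes in 5 groups of rising RNA level the median mark was -0.28, 0.09, 0.22, 0.25 and 0.31. The genes with the highest mean ratio were cys11 (1.29 ± 0.40, SD, n = 2), fis1 (1.23), nmd3 (1.19), trm11 (1.04) and phf1 (1.01), and the lowest were SPAC17A2.11 (-4.17 ± 0.70), mug124 (-3.75), mug114 (-3.71), SPAC110.06 (-3.58) and mug153 (-3.54). The arrays correlated with r = 0.897 across genes and shared 1 slide, so a slide effect could not be tested.

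**Figure D4:**
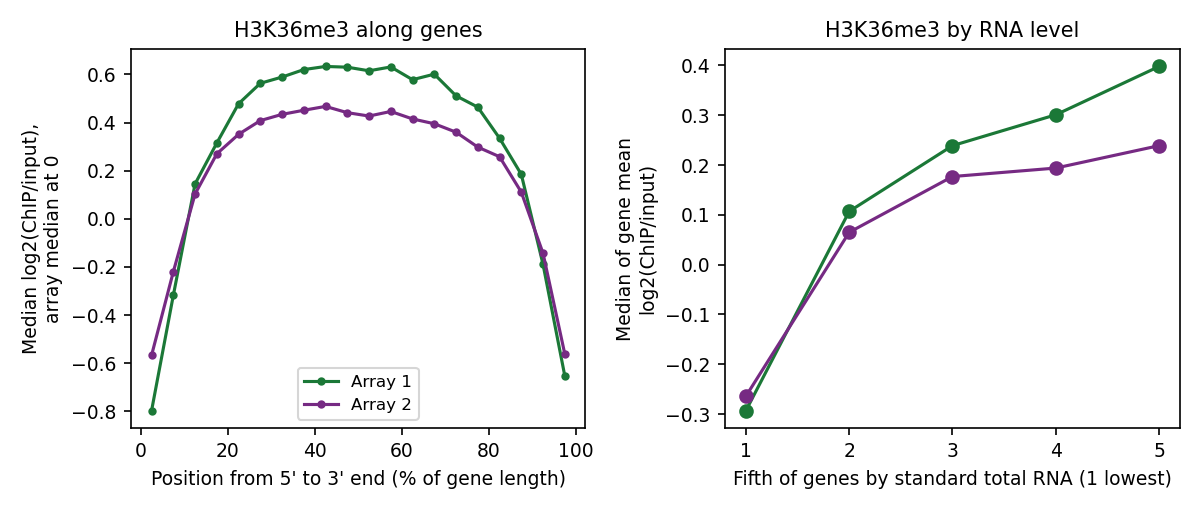
Median log2 ratio of H3K36me3 ChIP to input along coding genes of at least 1500 bases by position from 5' to 3' end (left) and over 5 groups of rising RNA level in standard total RNA (right), 1 line per array. On array 1 the mark was -0.80 at the 5' end, 0.63 near the middle and -0.65 at the 3' end, and over both arrays the median was -0.28 in the lowest and 0.31 in the highest group.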

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

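The count of zebrafish probes and the tests of additive background and of an effect of the experiment were chosen only after the results were seen. Each RNA array carries zebrafish probes, which served the report as a check of background and were not compared between groups there. After MMS 39 of 1084 of these probes were at least 4-fold above both standard samples, and in minimal medium 16 of 1083. At least 4-fold below both standard samples were 3 and 3 probes. Heat shock had 5 probes above and 4 below, and poly(A) RNA 6 above and 32 below. No explanation of these differences was tested.

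After MMS, ncRNA genes and antisense probes lay lower than in standard samples (3975 of 6064 ncRNA genes fell). If dim signal of any class had lain lower on the MMS arrays, coding genes of the same level would have fallen as much, but ncRNA genes lay at -0.26 relative to them (-0.27 and -0.24 in experiments 1 and 2, 95% bootstrap interval -0.31 to -0.21, 5820 genes), and at -0.27 with quantile normalisation. Coding genes of the same level fell as well. At standard levels of -3.0 to -2.5 their median was -0.384 and -0.487 in experiments 1 and 2. That of ncRNA genes was -0.598 and -0.653. At -4.0 to -3.5 both classes lay close in experiment 2 (-0.739 for 36 coding and -0.747 for 413 ncRNA genes). At -1.5 to -1.0 coding genes lay at -0.106 and -0.173 and ncRNA genes at -0.572 and -0.515. The difference between classes argues against dim signal as the whole cause, though not against a part of the fall. The medians of control spots and of zebrafish probes were at most 1.42% of the median antisense signal on the standard arrays, too little for a lower additive background to give the fall. An effect of MMS treatment on these transcripts, the lower culture density of the MMS cells and a difference between slides stay open and were not tested. Slide and condition cannot be told apart.

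Under heat shock, 388 of 523 antisense rises lay on genes whose sense signal rose and 37 on genes whose sense signal fell (r = 0.813 across 2631 genes). If antisense probes read a fixed share of sense signal, the share that 105 bright unchanged genes allow (0.98%) would give 18.3% of the median antisense rise of 388 genes (0.13 of 0.73), which argues against this as the main source. GC content shared by both strands is argued against as well, since r was 0.819 after regression on GC content (0.813 before, 2625 genes). Antisense transcripts that change with the sense transcripts, and transcripts of neighbouring genes that run across the probes, stay open and were not tested.

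Iron and copper uptake genes differed between both standard samples (str3, fip1, fio1, frp1, str1 and ctr4, median difference 1.88 on the log2 scale in the direction of each gene). Flawed spots on 1 array are argued against, since 100% of 215 probes of these genes shared the direction of their gene. An effect of the experiment on all total-RNA samples cannot be told apart from a difference of the standard cultures: the median difference between experiments was 0.21 in heat shock, -0.06 after MMS and 0.55 in minimal medium, the lowest of them -3.4% of that in standard samples, with 1 sample of each group per experiment. The design gives no group for a biological explanation, so none was tested. The fold changes of these genes against standard culture therefore rest on samples that differ.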

How the results depend on the processing

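Centring on coding genes in the treatments, testing coding genes only, the 99th percentile of zebrafish probes and list medians under each scaling were chosen only after the results were seen. The other alternatives were set before the data were examined.

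The counts of 5835 genes in heat shock, 6147 in MMS, 1682 in minimal medium and 8935 in poly(A) RNA stayed within 1.5 times under every alternative not named here. Slide design 1 alone, with fewer genes measured, gave 2995, 3075, 1034 and 4472 and design 2 alone 2836, 3070, 651 and 4469. A 2-fold minimum gave 2124, 1377 and 417 in the treatments. Testing coding genes only gave 3211, 1997 and 3728 in heat shock, MMS and poly(A) RNA. Quantile normalisation gave 3501 in MMS and 1714 between MMS and minimal medium (3896 before), and in minimal medium the fit of only the compared groups gave 787 and centring on coding genes 910; the cause was not tested. Leaving out each replicate, with the lone sample assumed to vary like the other groups, gave 4288 to 4815 in heat shock, 3602 to 4774 in MMS (3602 without MMS replicate 2, 3897 without standard replicate 1), 380 to 1172 in minimal medium (1033 without minimal medium replicate 2, 477 without standard replicate 1, 380 without standard replicate 2) and 8194 to 8525 in poly(A) RNA.

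Antisense counts were 1347, 2001 and 273. Quantile normalisation gave 541 in MMS and 156 in minimal medium; the cause was not tested. Without genes whose sense signal changed, so with fewer genes tested, 115, 1251 and 31 passed. Leaving out each replicate gave 937 to 1100 in heat shock, 1631 to 1716 in MMS and 52 to 190 in minimal medium (139 without minimal medium replicate 2, 113 without standard replicate 1, 52 without standard replicate 2), where the split of 75 higher and 198 lower became 62 and 77, 73 and 40, and 26 and 26.

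The experiment number as a replicate block gave 7117, 7543 and 3739 genes in heat shock, MMS and minimal medium, and 548 antisense changes in minimal medium. It ended no call of a named gene, added 19, and changed none of 49 list tests. No paired analysis was possible for poly(A) RNA because its arrays share no experiment number with total RNA. The other pairing of its arrays over both designs gave 8935 genes again.

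Of the list tests, 10, 12, 9 and 5 passed in heat shock, MMS, minimal medium and poly(A) RNA, and 1, 2, 2 and 2 with an estimated correlation between genes. The counts of 10 and 12 include the mitochondrial list, whose test is void. The coding and other ncRNA lists nearly complement each other, so in MMS and poly(A) RNA 1 contrast was counted under 2 lists. In poly(A) RNA only these 2 lists passed with an estimated correlation. Among coding genes, where fewer lists could be tested, 11, 8, 9 and 3 passed. There the respiratory (adjusted p = 0.155) and mitochondrial (adjusted p = 0.111) lists no longer passed after MMS, and the direction turned down for DNA repair (adjusted p = 0.804) and ribosomal proteins (adjusted p = 0.0143). Under other scalings 8 medians of lists that passed changed sign. Of all other medians 154 moved by more than their spread and 138 did not, and among these 14 medians of lists that did not pass also changed sign, such as glycolysis in heat shock (0.16, and -0.22 with quantile normalisation). The respiratory list in MMS (-0.03) lay at 0.111 scaled by detected probes, 0.051 centred on coding genes and 0.061 in the deposited table. In minimal medium the permease list (0.00) lay at -0.014 scaled by detected probes, and the glycolysis list (-0.00) at 0.065 with quantile normalisation, 0.135 centred on coding genes and 0.032 in the deposited table. Other ncRNA genes in poly(A) RNA lay at 0.149 with quantile normalisation. Named genes kept direction and side in 5145 tests, lost their call in 205 and gained one in 53. SPNCRNA.2101 turned to -0.019 with the mean of probes and rns to -0.278 with quantile normalisation, both in poly(A) RNA; the cause was not tested.

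The class shares depended on the threshold, and zebrafish probes set a high one: their 99th percentile was 1276 to 22518 on the total-RNA arrays, with medians of 11.8 to 23.1. Whether bright zebrafish probes bind yeast transcripts was not tested, so shares above them do not measure detection. Shares above background or above negative control spots do not by themselves measure transcription either. Above the 99th percentile of zebrafish probes lay 54.18% of coding, 10.25% of other gene, 23.58% of intron, 9.70% of antisense and 7.94% of intergenic probes in total RNA, and 93.14%, 39.34%, 63.87%, 17.34% and 24.82% in poly(A) RNA. Above the 99th percentile of negative control spots lay 99.53% of antisense probes in total RNA, and 98.23%, 87.69%, 90.29%, 70.56% and 62.27% of the classes in poly(A) RNA.

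The H3K36me3 difference of 3.13 between gene bodies and intergenic probes was 2.22 with normexp, 1.03 with loess and 2.28 in the deposited table. Between the last and first parts of 2581 genes, the difference passed with loess (0.044, permutation p = 0.0163) and was -0.003 on array 2 alone (permutation p = 0.877). The rho of 0.376 with RNA was 0.287 with loess, 0.351 on array 2 alone and 0.401 in genes of at least 1500 bases. The cause was not tested for these changes.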

Other observations

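The tests of lists not fixed for a comparison and of the length of poly(A) transcripts were chosen only after the results were seen, while the test of chromosome ends was set before its result was seen.

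Under heat shock 17 of 19 purine and pyrimidine synthesis genes fell and 1 rose (camera adjusted p = 3.05e-05, and adjusted p = 0.614 with an estimated correlation). On the amino acid synthesis list 42 of 77 genes fell and 4 rose (camera adjusted p = 0.00014, and adjusted p = 0.674 with an estimated correlation). The siderophore transporter gene str3 was counted among these falls. Of 10 histone genes 7 rose (camera adjusted p = 0.00152, and adjusted p = 0.614 with an estimated correlation). Their median was 0.84, and 0.19 with quantile normalisation. After MMS 12 of 20 metal and phosphate uptake genes rose and 3 fell (adjusted p = 1.37e-08, and adjusted p = 0.093 with an estimated correlation), and 9 of 23 chaperone genes rose and 2 fell (adjusted p = 2.17e-09, and adjusted p = 0.188 with an estimated correlation).

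In poly(A) RNA, shorter transcripts of coding genes stood higher relative to total RNA (Spearman rho of -0.678 between exon length and log2 fold change over 4966 genes, and -0.659 both without the ribosomal list and with quantile normalisation). At the exon lengths of the ribosomal list, its median was 2.30 (109 genes) and that of other coding genes 1.39 (650 genes).

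Genes near the ends of chromosomes I and II recurred among the named genes. A hypothesis was that genes within 100 kilobases of these ends changed more often than other coding genes of the same level. Of 54 such genes, 33 changed at least 2-fold under heat shock (16 rose and 17 fell) where 14.58 were expected from level-matched genes, 27 after MMS (18 and 9, 7.99 expected) and 24 in minimal medium (11 and 13, 3.71 expected). The lowest of the 3 ratios was 2.264, above the factor set for the test, so the values the hypothesis needs were there. As the pattern was found and tested on the same samples, it remains a hypothesis.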
